A study of Rattus norvegicus with 8 samples.

How the data were processed

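RNA from NR8383 cells, a rat alveolar macrophage line, was measured on 8 single-colour (Cy3) Agilent rat expression arrays. There were 4 biological replicates at passage 20 (P20) and 4 at passage 200 (P200), and the source of the replicates is known only as far as the labels state it. Cells were seeded 48 h before harvest, per the labels. All 8 arrays lie on 1 slide and were read in 1 scan, per the file headers.

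The deposited scanner files give the intensity of each spot on a linear scale, as processed signal, spot mean, spot median and local background. Per the file headers and the submitters' processing notes, the images were read with Agilent Feature Extraction 11.0.1.1, which subtracts background, removes spatial trends and replaces the signal of spots near background by a surrogate within each array. No normalization between arrays had been applied. The deposited series matrix holds the raw spot median intensity of the same arrays, without background subtraction or normalization, and 100.0% of its values equal the spot median of a scanner file. Its P20 columns match the scanner files of the same number. Its P200 columns 1, 2, 3 and 4 hold the arrays whose scanner files are numbered 2, 3, 4 and 1, so the group of every column is intact and the numbering inside P200 is not. Replicate numbers in the text are those of the scanner files.

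Each array carries 62976 spots, of which 4259 are controls and were left out. Outlier spots marked by the scanner software were left out, spots of the same probe were averaged, and 84 probes with no usable spot on some array were dropped, from 45598 distinct probes. Processed signal was taken to log2, and the 75th percentile of each array was subtracted. A probe entered if it was well above background, as the scanner software marks it, on all 4 arrays of at least 1 group, which left 19458 probes. A gene was represented by its probe with the highest mean log2 signal over all 8 arrays, which gave 15651 genes. Gene names came from the RefSeq table for assembly GRCr8 by transcript accession for 21109 probes and by symbol or synonym for 7108, while 17381 probes kept the name in the files. That table was used only for names and for which genes lie on the Y chromosome. Map positions are those the scanner files give on assembly rn4, and no rn4 sequence was held to check them.

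P200 was compared with P20 with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with no covariate, two-sided, with Benjamini-Hochberg adjustment over all 15651 genes and an adjusted p under 0.05 as the threshold. Changes are log2 of P200 over P20, with the moderated standard error (SE) and n = 4 arrays per group. Where a gene was well above background on all arrays of one group and on none of the other, its fold is given as a bound: on each dim array a value below the lowest well-above-background signal of that array was raised to that signal, and the mean of the bright group was compared with the mean of these values. The bound is relative to that lowest signal and is not a strict limit, since a spot not well above background can lie above it. Cdkn2a did so on P200 replicate 4, at -3.629 against a lowest signal of -4.133, and its fitted fold is given. Dim signals limit the precision of all other folds near background, and the number of arrays limits the precision of every value.

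A total of 29 gene lists were fixed with 871 entries, of which 850 were found on the array: general macrophage lineage, alveolar macrophage, phagocytic receptors, cytokines and chemokines, Toll-like receptors and NF-kappaB, interferon response, antigen presentation, lysosome, NADPH oxidase, NRF2 and metal response, unfolded protein and heat shock response, eicosanoids, adhesion and migration, mitosis, DNA replication, p53 and senescence, DNA repair and telomeres, epigenetic writers, glycolysis and hypoxia, respiratory chain, sterols and lipids, xenobiotic metabolism, markers of lung epithelium, fibroblasts, endothelium, lymphocytes, granulocytes and mast cells, and dendritic cells, and Y-linked genes. The 25 lists with at least 5 measured genes were tested with limma's camera at its preset correlation of 0.01, adjusted over the 25 lists. Beside it stand camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way. Neither fry test compares a list with other genes. Some genes stand in several lists.

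The lists, tests, thresholds, the rule for named genes and the first set of alternative settings were set before the data were examined. The rule takes, among genes past the test with a symbol that is a name, well above background on all 8 arrays and with all 4 arrays of one group above all 4 of the other, the 6 largest rises and the 6 largest falls. It adds the 4 largest bounds in each direction among genes well above background on all 4 arrays of only one group. For each list it adds up to 3 members past the test with the largest change, or, where none passes, the member with the smallest unadjusted p. It names 80 genes, each counted once, and 1 of them is not reported. Genes outside the rule whose changes are given were chosen after their values were seen, and the text says so.

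The map of changes along the chromosomes was made after the gene values were seen. For it, 14695 genes had a position in the files and 956 had none. Each chromosome's median change was set against 10000 random lists of the same size and 1000 random lists matched on mean signal. A two-sided exact permutation test ran over the 70 assignments of the 8 arrays. Its value for an array was the median deviation of the chromosome's genes from their means, less that of all placed genes. Fisher's exact test, two-sided, compared the share of genes called higher. The p of the random lists of the same size, of the permutation test and of Fisher's test were adjusted over all chromosomes. The share of matched lists as far out was not adjusted. Windows of 25 genes moved in steps of 5 were compared with the most extreme windows of 1000 random gene orders. On chromosome 7 the break was placed where the step between the mean changes of the 2 sides, each change limited to 1 on the log2 scale, was largest relative to its error, and the SE of a segment's median is from resampling its genes, which are not independent replicates.

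The labels do not say that equal replicate numbers share a day or a culture, and the residuals of equal numbers do not pair under the numbers of the labels or of the series matrix, so no pairing was used. Alternatives covered background correction, between-array normalization, the background filter, the handling of several probes, the variance model, array weights, replicate number as a block, the thresholds, and leaving out each array. Slide row and column as terms, and the replicate block with the numbers of the series matrix, were added after the data were seen. The design was also tested on simulated data of 15651 genes with the spread of these arrays: 22% of genes changed 1.25-fold were recovered, 61.6% at 1.5-fold, 85.6% at 2-fold and 98.4% at 4-fold, with 4.7% false among the calls and 0 calls when nothing had changed. Each simulation changed 200 genes, fewer than were called in the real data, and drew the noise of each gene independently. Variation that genes share was therefore not covered. Extraction used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures used matplotlib 3.10.9.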

Results

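NR8383 is a rat alveolar macrophage line that grows as a mixture of attached and floating cells. Its gene expression was measured at a low passage number, passage 20 (P20), and at a high one, passage 200 (P200), on 4 arrays per group. Between 51.02% and 54.47% of the spots of an array were well above background, none was saturated, and the 75th percentile of processed signal ran from 978.75 to 1869.1. Across genes, which are not independent replicates, Pearson's r was 0.9926 to 0.9958 between P20 arrays, 0.9883 to 0.9966 between P200 arrays and 0.9766 to 0.9829 between the groups. The first principal component held 60.54% of the variance and parted the groups, and the second, with 13.9%, set P200 replicate 4 (-30.15) apart from P200 replicate 1 (20.02). The median SD between arrays of a gene's log2 signal was 0.108 at P20 and 0.144 at P200.

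The comparison of P200 with P20 asks how far prolonged culture goes with altered expression in this line. The chemokine Ccl7, which attracts monocytes, fell 15.3-fold (log2 change -3.93 ± 0.09 SE, n = 4 per group, adjusted p = 3.13e-08), and the neutrophil attractant Cxcl1 went from well above background on all 4 P20 arrays to above it on none at P200, at least 17.7-fold lower. The scavenger receptor Msr1, which takes up modified lipoproteins and bacteria, fell 8.52-fold (-3.09 ± 0.18, adjusted p = 7.87e-06). In the other direction Alox5ap, the protein that presents arachidonic acid to 5-lipoxygenase, was at least 31.6-fold higher at P200 (adjusted p = 2.33e-07) and above background on no P20 array. Of 15651 genes, 938 rose and 866 fell, 11.53% of those tested.

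Among genes well above background on all 8 arrays, the largest rises were those of Cox7b2 (4.76 ± 0.12, 27.1-fold, adjusted p = 5.77e-08), a relative of a cytochrome c oxidase subunit, and Smoc1 (4.65 ± 0.09, 25.1-fold), a secreted calcium-binding matrix protein. Their probes lie on chromosome 14 at 39267757 to 39267816 and on chromosome 6 at 105000336 to 105000395. Ms4a4a, a membrane protein of macrophages, rose 22.9-fold (4.52 ± 0.13), and Spocd1, known from germline DNA methylation, 10.8-fold (3.43 ± 0.07). Rpl10l1 (3.36 ± 0.08) and Erhl1 (3.32 ± 0.11) completed the 6 largest, and the Rpl10l1 probe was not shown to separate that gene from other copies of its ribosomal protein family. The largest fall was that of Bst1, an ectoenzyme that makes cyclic ADP-ribose (-4.44 ± 0.17, 21.8-fold, adjusted p = 3.88e-07), whose probe lies on chromosome 14 at 72404510 to 72404569. Ccl7 came next, followed by Tceal8 (-3.92 ± 0.21), the protein cross-linking enzyme Tgm2 (-3.75 ± 0.09, 13.4-fold), Msr1, and Dnph1 (-3.05 ± 0.14), which hydrolyses deoxynucleotides.

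With Alox5ap, 42 called genes were above background at P200 with no P20 array above it, and the next largest bounds were those of the RNA-binding protein Khdrbs3 (at least 10.2-fold, on distal chromosome 7), the focal adhesion protein Tns1 (at least 10.1-fold) and the sialyltransferase St6galnac3 (at least 10.1-fold). In the opposite sense 103 called genes were above background at P20 and on no P200 array. Ube1y1, a Y-linked gene for a ubiquitin-activating enzyme, was at least 1053-fold lower (adjusted p = 2.6e-08), Fam241b at least 38.2-fold, Arhgap26 at least 34.1-fold and the focal adhesion protein Tes at least 32.2-fold. Another probe of Fam241b gave -3.35. Each gene that the rule names as risen or fallen had all 4 arrays of one group above all 4 of the other.

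At least 2-fold changes numbered 198 up and 266 down, and at least 4-fold changes 82 up and 117 down. The 4 arrays of one group lay above the 4 of the other for 3062 genes, 19.56% against the 2.86% that chance gives, and for 1779 of the 1804 called genes. Centring on the array median in place of the 75th percentile left 286 rises and 367 falls and ended the calls of 26 named genes, those with changes smaller than that of Itgam. Testing all probes without the background filter left 389 rises and 423 falls. Because 3 of the 4 P20 arrays lie in one row of the slide and 3 of the 4 P200 arrays in the other, a fit with slide row as a block was made, and it called 1279 genes (660 up, 619 down).

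**Figure D1:**
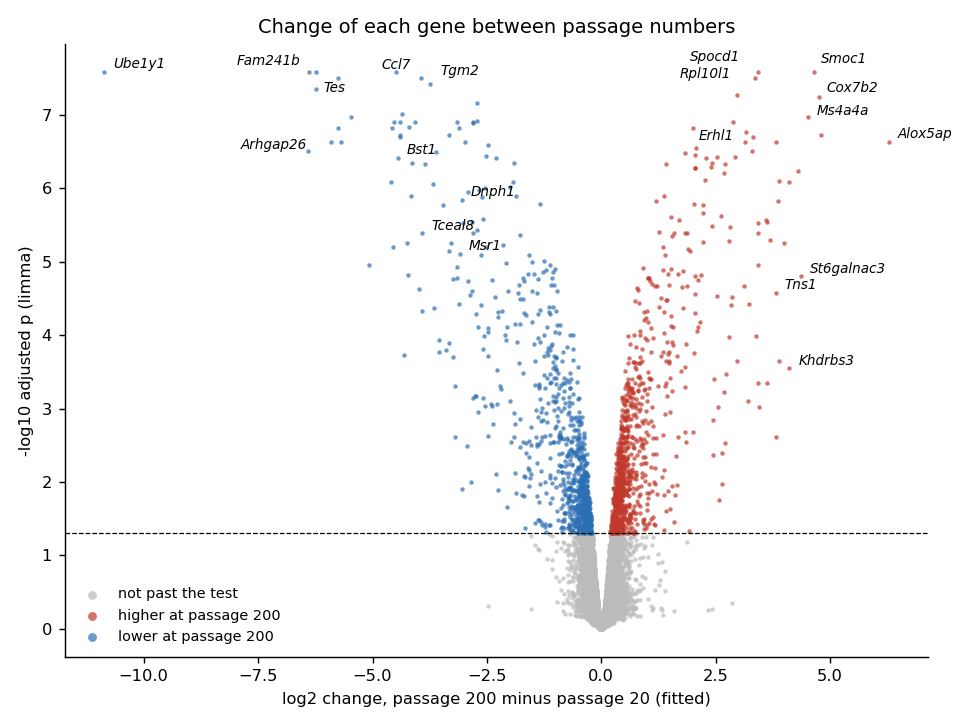
Fitted log2 change of P200 over P20 (x axis) against the negative log10 of limma's adjusted p (y axis) for 15651 genes, 4 arrays per group, with the threshold dashed. The 938 genes called higher are red, the 866 called lower are blue, and the genes with the largest changes are named; for genes above background in only one group the fitted change is not a bound.

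Cytokines, chemokines and inducible inflammatory enzymes fell together: of 27 measured, 17 fell, 2 rose and 8 did not pass the test. Adjusted over the list alone, 19 fell and 2 rose. Beside Cxcl1 and Ccl7, Cxcl3 (-2.99 ± 0.10, adjusted p = 2.33e-07) fell, and after the values were seen the neutrophil attractant Cxcl2 (-2.63 ± 0.20), the nitric oxide synthase Nos2 (-2.11 ± 0.18), Ccl5 (-1.70 ± 0.18), Ccl4 (-1.11 ± 0.08) and Tnf (-0.92 ± 0.13) were picked out as further falls. Platelet factor Pf4 was at least 7.39-fold lower and the adhesive cytokine Spp1 at least 3.5-fold lower, with no P200 array above background, and both were also picked after the values were seen. The 2 that rose, named after their values were seen, were Osm (0.92 ± 0.23) and Il18 (0.30 ± 0.07). Leaving out single arrays ended these calls in 6 and in 4 of 8 fits, with adjusted p up to 0.0927 and 0.0707. The list's median change was -0.70 (camera adjusted p = 3.79e-13, adjusted p = 0.094 with an estimated correlation).

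Interferon-stimulated genes also fell: 13 of 40 measured fell, 0 rose and 27 did not pass, against 21 falls adjusted over the list alone and 26 at an unadjusted p under 0.05. Gbp5, a guanylate-binding protein of antimicrobial defence, fell by 1.78 (SE 0.10), the antiviral enzyme Rsad2 by 1.57 (SE 0.23), Usp18, which removes ISG15 from proteins, by 1.13 (SE 0.21), and the transcription factor Irf7, picked after its value was seen, by 0.99 (SE 0.19). The median was -0.36 (camera adjusted p = 3.35e-09, adjusted p = 0.526 with an estimated correlation). The list of Toll-like receptors and the NF-kappaB pathway had 10 of 33 members lower, 1 higher and 22 not past the test, and 12 lower and 1 higher adjusted over the list alone. Tlr3, the receptor for double-stranded RNA, fell by 1.53 (SE 0.21), the RNA sensor Tlr7 by 0.68 (SE 0.14) and the NF-kappaB inhibitor Tnfaip3 by 0.56 (SE 0.10). The 1 member that rose, named after its value was seen, was the lipopolysaccharide receptor Tlr4 (0.40 ± 0.07). That list's median was -0.14 (camera adjusted p = 0.000289, adjusted p = 0.177 with an estimated correlation), and with the array median in place of the 75th percentile its adjusted p was 0.0877, the highest of 23 settings whose lowest was 5.13e-07.

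Antigen presentation genes fell in part: 8 of 24 measured fell, 0 rose and 16 did not pass, with 9 falls adjusted over the list alone and 10 at an unadjusted p under 0.05. The co-stimulatory receptor Cd40 was at least 3.92-fold lower, with no P200 array above background, and the class I gene RT1-A2 fell by 0.40 (SE 0.07), on a probe not shown to part it from other class I genes of the RT1 family. The median was -0.16 (camera adjusted p = 0.000289, adjusted p = 0.491 with an estimated correlation), and the adjusted p was 0.0825 with the array median, the highest of 23 settings whose lowest was 2.78e-05. These were the 4 lists of 25 past the test. With an estimated correlation 0 were, while 2 had an unadjusted p under 0.05, and fry called 7.

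**Figure D2:**
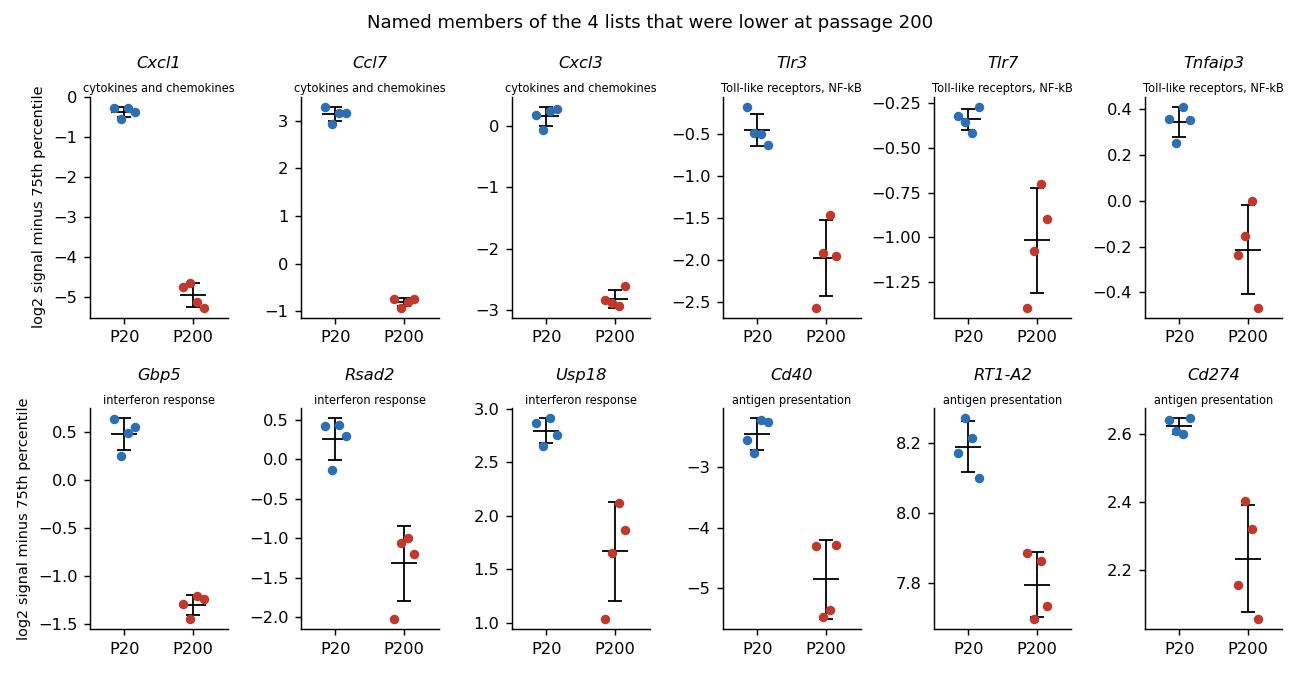
Log2 signal minus the array's 75th percentile (y axis, scaled to each gene) of the 12 named members of the 4 lists past camera's test at its preset correlation, on the 4 P20 arrays (blue) and the 4 P200 arrays (red), with bars for mean and SD. In each panel every P200 array lies under every P20 array, and for Cxcl1 and Cd40 no P200 array was well above background.

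Lineage genes moved in both directions. Of 22 general macrophage genes 2 rose, 2 fell and 18 did not pass, and the same numbers held when adjusted over the list alone. The lipopolysaccharide co-receptor Cd14 (-0.91 ± 0.13) and the integrin Itgam (-0.78 ± 0.13) fell. Csf2rb, a cytokine receptor subunit on the distal part of chromosome 7, named after its value was seen, rose by 0.57 ± 0.10. The median was -0.08, the mean 0.011 and the camera adjusted p = 0.466. Of 17 alveolar macrophage genes 4 rose and 2 fell, also adjusted over the list alone, and 11 did not pass. The lectin Siglec5 fell by 1.69 (SE 0.11) and the keratin gene Krt79, on distal chromosome 7, rose by 0.69 ± 0.09. Their median was 0.06, their mean -0.006 and the camera adjusted p = 0.425.

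Uptake receptors, lysosome and oxidase genes were mostly not past the test. Of 19 phagocytic receptors 3 fell (Msr1, Itgam and the oxidised-lipoprotein receptor Olr1, -1.41 ± 0.29, above background on 3 P200 arrays), 2 rose and 14 did not pass, with 7 lower and 3 higher adjusted over the list alone. The rises, named after the values were seen, were those of Tyro3 (0.66 ± 0.07), a receptor for apoptotic cells, and the lipoprotein receptor Scarb1 (0.51 ± 0.05). The median was -0.17 and the camera adjusted p = 0.18, or 0.0451 without P200 replicate 3, within a range of 0.000917 to 0.476 over 23 settings. Of 33 lysosomal genes 3 fell and 1 rose, also adjusted over the list alone, and 29 did not pass: the cathepsins Ctsh (-0.56 ± 0.09) and Ctsc (-0.39 ± 0.06) fell and the thioesterase Ppt1 (0.41 ± 0.07) rose, with a median of -0.03 and a camera adjusted p = 0.368. Of 16 NADPH oxidase and superoxide genes 2 rose, 0 fell and 14 did not pass, also adjusted over the list alone, with 4 at an unadjusted p under 0.05. Both, the oxidase subunit Ncf4 (0.61 ± 0.12) and its regulator Rac2 (0.46 ± 0.09), lie on distal chromosome 7. The median was -0.05, the mean 0.013 and the camera adjusted p = 0.988.

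Stress genes fell in part. Among 29 NRF2 and metal-response genes 6 fell, 1 rose and 22 did not pass, with 6 lower and 2 higher adjusted over the list alone. The metallothioneins Mt2A (-1.79 ± 0.13) and Mt1 (-1.13 ± 0.10), which bind zinc and whose probes were not shown to separate their similar sequences, fell, as did the haem-degrading enzyme Hmox1 (-0.42 ± 0.08), named after its value was seen. The median was -0.04 and the camera adjusted p = 0.18. Of 30 unfolded protein and heat shock genes 2 fell, 0 rose and 28 did not pass, also adjusted over the list alone, with 9 at an unadjusted p under 0.05. The chaperone Hspa1a, which has a near-identical copy, was at least 2.84-fold lower. The median was -0.08 and the camera adjusted p = 0.203.

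Eicosanoid genes split: of 13 measured 3 rose, 2 fell and 8 did not pass, also adjusted over the list alone. Beside Alox5ap, the prostaglandin receptor Ptger4 rose by 1.41 ± 0.15, with 3 P20 arrays above background. The median of this list was -0.02, its mean 0.52, and camera put it higher (adjusted p = 0.988), while it passed with the array median (adjusted p = 0.00208) and with fry (adjusted p = 0.0026). Of 28 adhesion and migration genes 7 fell, 6 rose and 15 did not pass, with 8 lower and 6 higher adjusted over the list alone. The metalloprotease inhibitor Timp1 (-3.33 ± 0.11) and the matrix protease Mmp2 (-1.89 ± 0.16), each above background on 1 P200 array, fell by sizes that rest on mostly dim P200 values, and the protease Mmp7 rose by 2.23 ± 0.11. Mmp9 (-1.37 ± 0.18) and the chemokine receptor Ccr1 (-1.18 ± 0.14), both named after the values were seen, fell too. The median was -0.05 and the camera adjusted p = 0.346.

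Few cell cycle genes passed the test. Of 34 mitotic genes 0 passed the limma test, adjusted over the list alone or over all genes, with 1 at an unadjusted p under 0.05 (Racgap1, 0.22 ± 0.07, adjusted p = 0.0992, on distal chromosome 7). Their median was -0.03, their mean 0.004, and camera put them higher (adjusted p = 0.988). Of 38 DNA replication genes 1 rose, 0 fell and 37 did not pass, 0 did adjusted over the list alone and 4 had an unadjusted p under 0.05, with a median of 0.03 and a camera adjusted p = 0.198. Of 24 p53 and senescence genes 3 rose, 1 fell and 20 did not pass, with 5 higher and 1 lower adjusted over the list alone. Cdkn2a, which encodes inhibitors of the cell cycle, was 9.7-fold lower as fitted (adjusted p = 5.55e-06), with no P200 array above background. None of its P200 values was low enough to be raised, so no bound is given and this size rests on dim values. The chromatin protein Hmga1 rose by 0.42 ± 0.08. The median was 0.06, the mean -0.056 and the camera adjusted p = 0.425. Of 40 DNA repair and telomere genes 1 rose, 1 fell and 38 did not pass, also adjusted over the list alone: Dkc1, needed for telomerase RNA, fell by 0.62 (SE 0.09), and Xrcc6, of the Ku end-joining complex and on distal chromosome 7, rose by 0.32 ± 0.05, with a median of 0.018 and a camera adjusted p = 0.741. Among 22 epigenetic writers 3 rose, 0 fell and 19 did not pass, also adjusted over the list alone, with 4 at an unadjusted p under 0.05. The DNA methyltransferase Dnmt3b rose by 1.09 ± 0.12 and the acetyltransferase Ep300, on distal chromosome 7, by 0.39 ± 0.07, with a median of 0.05 and a camera adjusted p = 0.256.

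Metabolic genes were largely not past the test. Of 26 glycolysis and hypoxia genes 1 fell, 0 rose and 25 did not pass, also adjusted over the list alone. The lactate exporter Slc16a3 was at least 23.8-fold lower (adjusted p = 1.11e-05), the list median was -0.07 and the camera adjusted p = 0.189. Of 39 respiratory chain genes 2 rose, 0 fell and 37 did not pass, also adjusted over the list alone, with 4 at an unadjusted p under 0.05. They included the complex I subunit Ndufb9 (0.39 ± 0.07), on distal chromosome 7, and the median was 0.04 (camera adjusted p = 0.346). Of 33 sterol and lipid genes 1 rose, 1 fell and 31 did not pass, with 1 lower and 0 higher adjusted over the list alone. The fatty acid importer of mitochondria Cpt1a fell by 0.43 (SE 0.09), and the median was 0.02 while camera put the list lower (adjusted p = 0.988). Of 14 xenobiotic genes 1 rose, 1 fell and 12 did not pass, with 2 higher and 1 lower adjusted over the list alone. The drug efflux pump Abcb1b fell by 2.48 (SE 0.21), above background on 1 P200 array, so that this size too rests on mostly dim values, and the median was 0.06, the mean -0.078 and the camera adjusted p = 0.622.

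Markers of other cell types were mostly not above background. Surfactant genes Sftpa1, Sftpb and Sftpd and the epithelial Epcam and Cdh1 were above background on 0 arrays, and of 4 measured lung epithelial markers the tight junction gene Cldn18 was called lower (adjusted p = 3.65e-06), its probe above background on 0 P200 arrays so that no fold is given, with 3 not past the test. Of 3 fibroblast markers measured 0 passed the limma test and 0 had an unadjusted p under 0.05 (Dcn 0.21 ± 0.10, adjusted p = 0.235). Of 5 endothelial markers, which include the adhesion gene Pecam1, 1 rose and 4 did not pass: the growth factor receptor Flt1 (adjusted p = 0.00402, its probe above background on 0 P20 arrays, so no fold is given), with a list median of 0.15 and a camera adjusted p = 0.18, or 0.00998 with the array median and 0.0194 with the mean of a gene's probes. Of 6 lymphocyte markers 1 rose, Cd4 (1.20 ± 0.19), which rat macrophages also carry, and 5 did not pass (median 0.12, camera adjusted p = 0.352). Of 3 granulocyte and mast cell markers the antimicrobial peptide gene Camp fell by 1.13 (SE 0.09) and 2 did not pass. Of 6 dendritic cell markers 3 fell and 3 did not pass, among them the transcription factor Batf3 (-1.47 ± 0.09) and the lectin Clec9a (-0.88 ± 0.13), with a median of -0.18 and a camera adjusted p = 0.18. The counts for these 6 lists were the same adjusted over the list alone.

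A further 11 genes that the rule names passed the test with all 8 arrays and not without single arrays. Cd274, an inhibitory ligand of T cells (-0.39 ± 0.08), lost its call without P20 replicate 1 (adjusted p = 0.0505), and the cytochrome Cyc1 (0.31 ± 0.07, on distal chromosome 7) without P20 replicate 2 (0.0518) or 3 (0.0579). Klf4 (0.43 ± 0.09) lost it without P20 replicate 3 or 4 or P200 replicate 3, with adjusted p up to 0.0584. The calls of Atf3 (-0.36 ± 0.09, adjusted p up to 0.0747) and the repair glycosylase Ung (0.29 ± 0.07, up to 0.0834) each ended in 5 of 8 such fits: the former without any P20 replicate or P200 replicate 3, the latter without P20 replicates 1, 2 or 3 or P200 replicates 2 or 3. Ephx1, an epoxide hydrolase (0.72 ± 0.17, up to 0.0773), lost its call without P20 replicates 1 or 3 or P200 replicates 2, 3 or 4, and the cyclooxygenase Ptgs1 (0.77 ± 0.18, up to 0.0791) also without P20 replicate 4. The antigen-presenting Cd1d1 (-0.37 ± 0.10, up to 0.105) lost it without any P20 replicate or P200 replicates 1 or 3. The inhibitor Cdkn2b (0.48 ± 0.12, up to 0.106), the deacetylase Sirt1 (0.33 ± 0.09, up to 0.127) and the sterol regulator Srebf2 (0.58 ± 0.15, up to 0.0975, on distal chromosome 7) kept theirs only without P20 replicate 3, P200 replicate 4 and P200 replicate 2 in turn. Over all 1804 called genes, 1125 passed in all 8 of these fits and 27 in none.

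**Figure D3:**
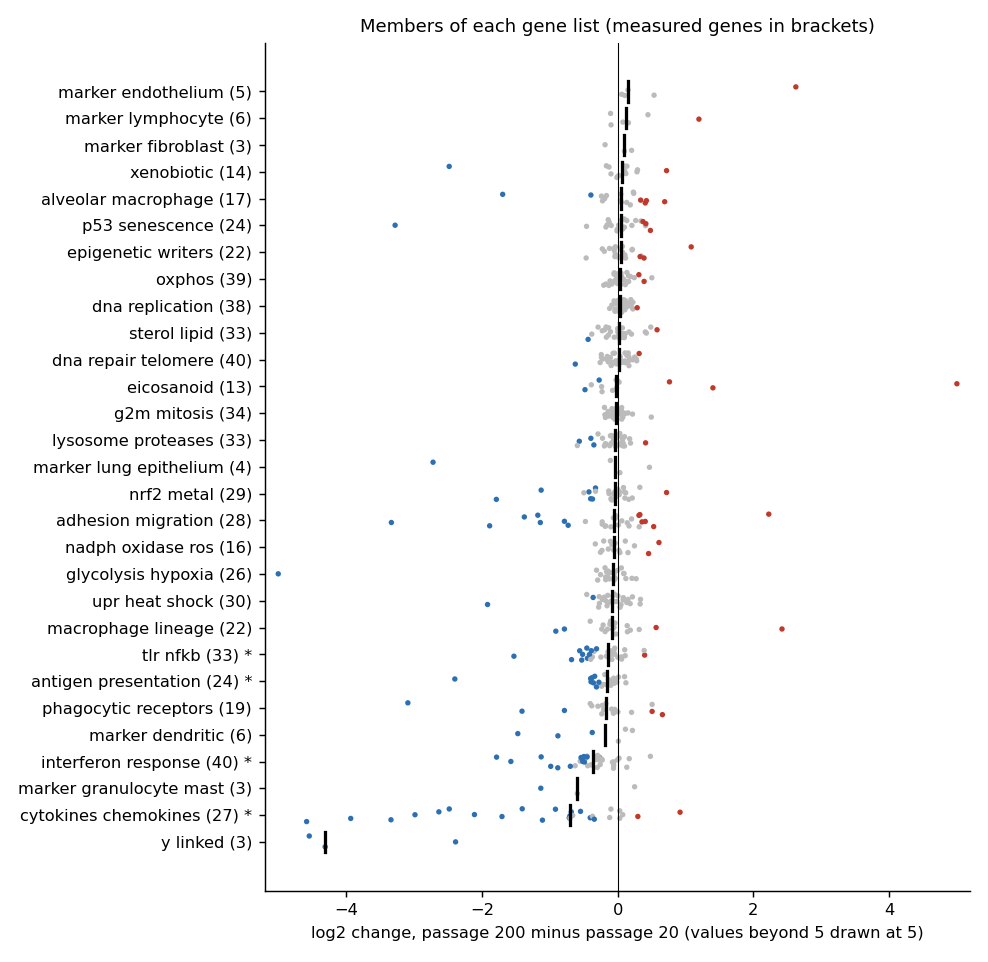
Log2 change of P200 over P20 for every measured member of each of the 29 lists, with called members in red (higher) or blue (lower), a black bar at the list's median, and an asterisk for the 4 lists past camera's test at its preset correlation, none of which passes with an estimated one (smallest adjusted p = 0.094). The cytokine, interferon, antigen presentation and Toll-like receptor lists have medians of -0.70, -0.36, -0.16 and -0.14, and genes above background in only one group are drawn at their fitted value.

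Y-linked genes were far lower at P200. The list's 3 measured members all fell, adjusted over the list alone as well: the translation factor Eif2s3y was at least 13.3-fold lower, the histone demethylase Kdm5d at least 10.1-fold lower, and the RNA helicase Ddx3y fell by 2.39 (SE 0.16), with another probe at -3.93 and with a close relative on the X from which its probes were not shown to part it. After these values were seen, the reference table was searched for every Y gene. Of 19 on the array 6 were measured, all 6 well above background on the 4 P20 arrays, and 6 fell; 4 of them had prompted the search, so no test of their share is given. The others were Ube1y1, LOC103694537 (at least 20.2-fold lower) and LOC103694571 (-1.35 ± 0.12), whose probe the files place on chromosome 7. At P200 4 of the 6 were above background on no array, and Ddx3y and LOC103694571 on all 4.

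Genes of distal chromosome 7 shifted upwards together, a comparison made after the gene values were seen. On chromosome 7, with 936 placed genes, 266 rose and 35 fell, so that 28.4% rose, and the median change was 0.15. Split into 4 equal parts in map order, its genes had medians of 0.006, 0.024, 0.30 and 0.33. The break lay between 62871512, in Usp15, and 65717814 on rn4. Before it, 379 genes had a median of -0.019 (SE 0.009), with 15 higher and 21 lower. After it, 557 genes up to the chromosome's end at 142428664 had a median of 0.31 (SE 0.01), 1.24-fold, with 85.3% above 0, 251 higher and 14 lower. All 4 P200 arrays (mean 0.165, SD 0.038) lay above all 4 P20 arrays (mean -0.159, SD 0.010) over that segment. The cell growth regulator Myc (0.59 ± 0.07, adjusted p = 0.000491) and the galectin Lgals1 (2.71 ± 0.10), both picked after their values were seen, lie on it.

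For the whole chromosome the random lists gave p = 1e-04, the smallest they can give (7e-04 adjusted), and Fisher's exact test of the share that rose gave an adjusted p = 2.06e-113. Both take genes as units, which are not independent replicates, and neither measures the spread between cultures. The exact permutation test over arrays gave p = 0.0286, the smallest that 4 against 4 arrays allow, and 0.086 adjusted over the chromosomes, which does not pass. It could have passed only if most chromosomes had reached that smallest p. Chromosomes 5, 15, 16 and 17 share both values, so the adjusted test cannot single out chromosome 7. Chromosomes 2 (-0.034) and X (-0.044) also lay apart from random lists (adjusted p = 7e-04), with 0.086 in the adjusted exact test. Of 2848 windows of 25 genes 109 lay above the limit of 0.206 from random orders, 101 of them on chromosome 7, and 12 below -0.188. Without chromosome 7, 625 of 13759 genes rose and 761 fell.

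**Figure D4:**
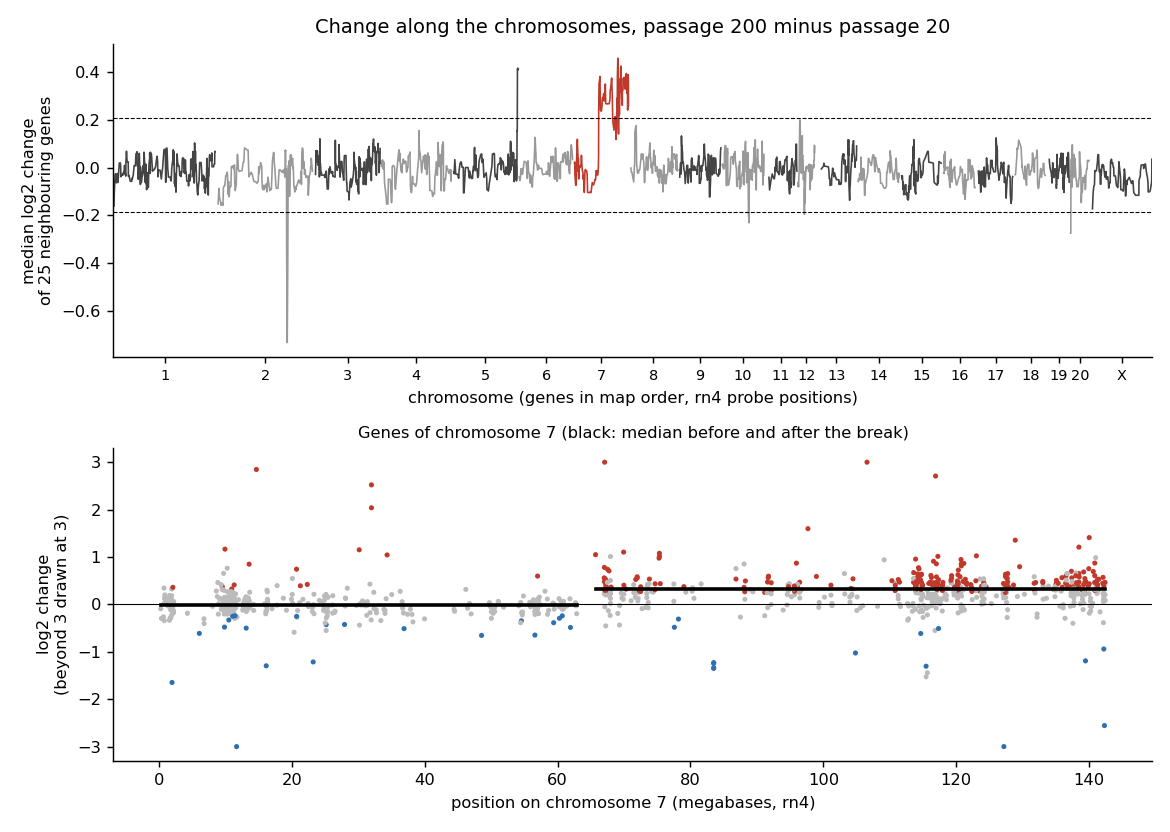
Upper panel: median log2 change of windows of 25 neighbouring genes (y axis) along the chromosomes in map order (x axis), with dashed limits of 0.206 and -0.188 from 1000 random gene orders. Lower panel: log2 change of each gene of chromosome 7 by position on rn4, called genes in red (higher) or blue (lower), with black bars at the medians of -0.019 before and 0.31 after the break.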

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

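Among the tests of this part, those on the Y genes, on the distal segment of chromosome 7 and on a shared state of the cultures were chosen only after the result was seen.

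Y-linked genes were lower at P200 in all 6 cases measured: every Y gene of the reference table that was well above background on the P20 arrays was called lower, as loss of the Y chromosome from most P200 cells needs, though 4 of the 6 had prompted the test. The files place the probe of LOC103694571 on distal chromosome 7, where it was also counted as a gene of that segment. Ddx3y and LOC103694571 kept signal well above background on all 4 P200 arrays. Loss from nearly all cells would not leave such signal unless their probes also read other genes, which was not tested. The tables argue against normalization or signal correction as the cause for 5 of the 6, and all 6 stayed called under 5 other signal settings (largest adjusted p = 0.00113). LOC103694571 fell by 0.762 with a background correction that adds an offset and by 0.887 with the series matrix values, both under the bound of 1 written for that test, so for this gene it stays open how much of the fall is signal handling, while the other 5 fell by at least 1.391. A P200 culture that came from another animal cannot be told apart from loss in culture: 99 genes off the Y were also lower and above background on no P200 array, and no DNA or genotype was measured. Loss of the Y in culture may account for the pattern, as a hypothesis, and silencing of its genes was not tested.

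The upward shift on chromosome 7 does not cover the whole chromosome: the smallest median among its 4 equal parts was 0.006, against 0.33 in the last. The criterion first written, a like sign in all 4 parts, was met and was too weak to test a gain of the whole chromosome, because a gain would put all parts near one value. Signal handling and array position did not remove the shift, whose smallest size under those settings was 0.122 for the whole chromosome, and 0% of random lists matched on mean signal lay as far out. A gain of the distal segment needs a similar shift at every expression level, and its lowest median among 3 groups of genes by mean signal was 0.277 against 0.31 for the segment. A distal gain in the P200 cells is a candidate explanation, which a measurement of DNA copy number would test and RNA alone leaves open.

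The inflammatory lists that were lower at P200 did not follow the position of the arrays on the slide: with slide row and column in the fit each of the 4 kept at least 104.3% of its median change. Nor did they rest on P200 replicate 4, without which each kept at least 100.3%. What stays open is a state shared by the cultures of one group other than passage number, such as density or activation at harvest, which may move these correlated genes together. With an estimated correlation the smallest adjusted p of the 4 lists was 0.094. That correlation is taken from differences between arrays of the same group, so this value cannot decide on a state that differs between the groups. The labels give the same seeding and growth time for both groups and no state measured at harvest, so such a state and passage number cannot be told apart.

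Of the 35 ways to split the 8 arrays into 4 and 4, only the real one (1 split) gave as many called genes, with 1804 against 0 for the highest of the others. Every other split mixes arrays of both passage numbers, so the difference between the groups enters its error. The 0 calls of those splits are therefore no measure of chance, and the comparison does not exclude it. Chance cannot be excluded for the number of lists either: 16 of the 35 splits gave as many, with 4 lists in the real split and 8 in the highest of the others. That highest split has 3 P20 arrays on one side, so it still carries part of the difference between the groups. The count of lists thus cannot set chance apart from passage number. In that count lists of correlated genes were called along other divisions of the arrays.

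Single arrays lay apart from the other 3 of their group in 9 of 216 groups of named genes and list means, where chance flags about 1 in 20 groups, or 10.8 here. Values are log2 signal minus the array's 75th percentile, and the gap is the distance to the nearest other array over the range of the group. Atf3 stood at 3.14 on P200 replicate 4 against 3.44 to 3.47 on the others (gap 0.896). Flt1 was at -2.40 on the same array against -1.69 to -1.57 (gap 0.86). Kdm5d was at -4.09 on it against -6.10 to -5.80, all not well above background (gap 0.852). The mean of the alveolar macrophage list was 4.21 on P200 replicate 1 against 4.39 to 4.42 (gap 0.873), and that of the lysosome list 3.95 on the same array against 4.11 to 4.14 (gap 0.853). The cytokine and chemokine mean was 1.5 on P200 replicate 2 against 1.57 to 1.58 (gap 0.898). On P20 replicate 3 the mean of the mitotic list was 2.23 against 2.36 to 2.38 (gap 0.834) and that of the dendritic cell list 1.26 against 1.42 to 1.44 (gap 0.864). On P20 replicate 2 the glycolysis and hypoxia mean was 3.90 against 3.99 to 4.00 (gap 0.859).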

How the results depend on the processing

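The slide terms and the replicate block with the numbers of the series matrix were chosen after the data were seen. No called list or named gene reversed under any setting run; of all 1804 called genes 3 had the opposite sign without the filter and 2 with the mean of a gene's probes. The array median in place of the 75th percentile left 653 called genes (286 higher, 367 lower) and ended the calls of the Toll-like receptor and NF-kappaB list (-0.177, adjusted p = 0.0877) and of antigen presentation (-0.193, adjusted p = 0.0825), while the eicosanoid list (adjusted p = 0.00208) and the endothelial markers (adjusted p = 0.00998) came past the test. Only 51.02% to 54.47% of an array's spots were well above background, and the median processed signal was 26.57 to 42.07. This setting thus centres each array on a signal close to background. Whether that made the difference was not tested. Without a background filter, which tests 36121 genes in place of 15651, 812 were called (389 higher, 423 lower) and 11 lists. Asking for a 2-fold change left 464 (198 higher, 266 lower) and an adjusted p under 0.01 left 936 (493 higher, 443 lower), both by construction. The remaining settings gave 1249 to 2444 called genes, among them 1506 with normexp, 1864 with quantile normalization, 1504 with the values of the series matrix, 2444 with array weights, and 1333 with slide row and column, where 7 lists were called and the cause was not tested. Leaving out 1 array at a time gave 1269 to 1694 called genes, 674 to 861 higher and 595 to 836 lower, with 4 to 5 lists.

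With replicate number as a block 1503 genes were called (785 higher, 718 lower), and 1249 with the numbers of the series matrix. The deviations of equal numbers from their group means correlated across genes, which are not independent replicates, at r = 0.025, 0.134, -0.003 and 0.281, and at 0.225, 0.066, 0.099 and -0.111 with the numbers of the series matrix, so neither numbering gives 4 pairs that all correlate above 0.1. Slide as a block was not run, since there is 1 slide. With an estimated correlation 0 lists passed camera's test, 2 had an unadjusted p under 0.05, and fry called 7. For cytokines and chemokines, Toll-like receptors, interferon response and antigen presentation the estimates were 0.098, 0.027, 0.367 and 0.122. These exceed the preset 0.01, which widens the error. How much of the loss of calls this explains was not tested. The heat shock list, at -0.006, also went from an unadjusted camera p of 0.0891 to 0.102. In the same order the medians of the 4 lists were -0.70, -0.14, -0.356 and -0.156 as before. Over the other 23 settings these medians ran from -0.795 to -0.443, -0.185 to -0.106, -0.456 to -0.277 and -0.249 to -0.101. Lists not called came past the threshold in 16 combinations of list and setting, and in 1 that left out an array: those of phagocytic receptors, lysosome, NRF2, heat shock, eicosanoids, adhesion, glycolysis, endothelium and dendritic cells. Named genes lost their call in 139 combinations of gene and setting and in 54 that left out 1 array. Among the 139 were 26 with the array median, 25 without the filter, 9 with slide row as a block and 12 with slide row and column. The spread between P20 arrays was 0.108, and 0.094 with normexp, whose offset shrinks dim signals. No setting moved the median of all genes by over 0.1, the largest being 0.0972 without the filter. Signal over background limits folds of dim genes, and of the smallest simulated changes 22% were recovered.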

Other observations

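The genes in this part were picked after their values were seen. Of 8 measured genes whose symbols begin with Mage, all with probes on the X, 3 rose, 2 fell and 3 did not pass; no list of them was fixed beforehand and no test of the family was made. Mageb4 rose by 2.69 ± 0.11 (SE, n = 4 per group, adjusted p = 6.21e-07), Magea14 by 2.05 ± 0.07 (adjusted p = 3.5e-07), and Mageb18 was at least 6.38-fold higher and above background on no P20 array. Magec2 was at least 2.67-fold lower and above background on no P200 array, and Magea4 fell by 1.69 (SE 0.31, adjusted p = 0.00838).

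A second stretch of raised genes lay at the end of chromosome 5, from 169535537 to 173056425 on rn4. Its 60 genes had a median change of 0.38 (SE 0.04), with 29 higher and 1 lower. Like the lower stretches below, it was chosen as a run of windows beyond the limits from random orders. Its median and counts therefore follow in part from that choice. The SE, from resampling the chosen genes, does not allow for it. The peroxiredoxin-like Prxl2b rose by 2.06 ± 0.07, the matrix protein gene Agrn by 0.75 ± 0.10, the transcriptional regulator Ski by 0.52 ± 0.07 and the Wnt signalling gene Dvl1 by 0.49 ± 0.06. A lower stretch lay on chromosome 10 (median -0.163, SE 0.064), where 13 of 40 genes fell, among them Ccl3 (-0.70 ± 0.08) and Ccl4 beside Ccl7. On chromosome 12 (median -0.196, SE 0.08) 7 of 25 fell. On chromosome 20 (median -0.202, SE 0.083) 10 of 35 fell, several of them class I genes of the RT1 family. On chromosome 2 from 182896189 to 189898861 (median -0.154, SE 0.094), 13 of 40 genes fell. Among them were Lce1e (-1.12 ± 0.07), Lce1f (-1.05 ± 0.08) and Lce1m (-1.01 ± 0.06), near-identical epidermal genes whose probes were not shown to measure them separately. The medians of the chromosome 2 and 10 stretches as wholes did not reach the window limit of -0.188.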
